A study of Homo sapiens with 10 samples.

How the data were processed

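Broad peak lists from ChIP-seq of T47D-derived DBM cells were analysed for 8 libraries. They cover H3K9ac, H3K27ac, H3K27me3 and H3K9me3, each in cells with a control shRNA and with an shRNA against MSK1. Per the labels, chromatin was sonicated, immunoprecipitated with commercial antibodies from Abcam (H3K9ac, H3K27me3 and H3K9me3) or Millipore (H3K27ac), and made into Illumina libraries. Groups were taken from the sample titles. The series has 10 libraries, of which the 2 input libraries were not used here.

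The submitters' processing notes name the genome build hg19 and the programs Bowtie (version 1.0.1), HOMER (version 4.6) and MACS2, without saying what each was used for. The MACS2 version, the calling cutoffs, the control used and the handling of duplicate reads are not given in the sources used here. Peaks were called per sample, 1 deposited list for each. The deposited fold enrichment of each peak is a linear ratio over the local background, averaged over the broad region. The deposited −log10 p and −log10 q are those of the authors' peak caller, averaged in the same way. The deposited score is a whole number that equals 10 times −log10 q, rounded down, in nearly all rows, and it was not used further. All 8 lists hold peaks with a −log10 q of 1 or more and a width of at least 300 bp. Because a q limit corresponds to a different p limit in each list, the lowest −log10 p ran from 2.45 in shMSK1 H3K9me3 to 3.18 in shMSK1 H3K27ac. A broad peak caller finds more and longer peaks in a library with more reads or better enrichment, so peak numbers and lengths reflect these as well as the mark.

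Read depth is unknown, since the lists hold no read counts. A background level was derived for each list from peaks under 450 bp, by solving for the local background that gives both the listed fold enrichment (with a pseudocount of 1) and the listed Poisson p, and taking the 10th percentile. It was 5.43 in shCTRL and 4.73 in shMSK1 for H3K9ac, 5.41 and 4.32 for H3K27ac, 4.78 and 5.17 for H3K27me3, and 5.15 and 4.79 for H3K9me3, in reads per fragment length. The lower edge of these values was blurred in shCTRL H3K27me3, shMSK1 H3K9ac and shMSK1 H3K27ac, where the level may be too low. The background level of a chromosome was instead the median over the short H3K9ac peaks of both lists together.

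Peaks were used as listed, and positions are given counting from 1. A peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Shares are given with exact 95% Clopper-Pearson intervals, which cover counting error only and treat peaks as independent. The chance level was the mean of 100 rotations, in which all peaks of a chromosome were shifted by the same random distance; assembly gaps were not excluded. Long stretches were formed by joining peaks less than 3 kb apart. With 1 library per group there was no test between cell lines, and no p-value was computed across peaks. The permutation tests of the closing section are over chromosomes, with 100000 permutations. The overlap and background calculations were tested on simulated data: for the 33490 shCTRL H3K27ac peaks the simulated share overlapped was recovered with an error of 0, and 3 simulated background levels were recovered. These simulations checked the arithmetic only. Kept peaks were shifted by less than their width. Simulated fold and p came from the formula being solved, for single sites, while the listed values are averages over a region.

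Comparisons of peak number, covered length, overlap and exchange between marks were fixed before the data were examined, with the alternatives of a −log10 q of at least 2 or 5, joining peaks less than 3 kb apart, an overlap of at least 50% of the peak, and lists of equal length by fold enrichment. Limits of a −log10 p of at least 4 and a fold enrichment of at least 3.5 were added after seeing the data. The analyses by fold enrichment, by H3K9ac, by chromosome, of long stretches, of gained bases and of distance to the nearest peak were also chosen after seeing the data.

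Promoters, gene lists and named genes, including RPS6KA5, were to be analysed too, but the gene table used here belongs to GRCh38 while the peaks are in hg19. Coordinates were not converted, so these are not analysed here. Regions were named instead by the rule fixed for this case, the 3 widest peaks per mark found only in shCTRL and the 3 widest found only in shMSK1, of which the text gives those that matter most. The widest peak of each list and the longest joined domain were named after their values were seen. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.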

Results

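Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map 4 modifications of histone H3 in dormant bone metastatic (DBM) cells, a derivative of the luminal breast cancer line T47D. The cells carried either a control short hairpin RNA (shCTRL) or one directed at MSK1 (shMSK1), a nuclear kinase encoded by RPS6KA5 that phosphorylates histone H3. H3K9ac is typical of active promoters, and H3K27ac of active promoters and enhancers. H3K27me3 is deposited by Polycomb complexes, and H3K9me3 is typical of heterochromatin. The comparison asks how the chromatin state of these cells differed when MSK1 was reduced. Each mark was measured in 1 library per cell line, giving 8 peak lists, and 2 input libraries were not analysed here. With 1 library per group, no difference has a replicate check and no test between the cell lines was possible. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only. Read depth is unknown, and the knockdown itself was not measured in these lists. Fold enrichment is the authors' value for each peak. Positions are in hg19, and genes at them were not analysed here.

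The shMSK1 lists held fewer acetylation peaks and more methylation peaks than the shCTRL lists. H3K27ac peaks numbered 33490 in shCTRL and 18878 in shMSK1, a ratio of 0.564, and covered 57.9 and 32.2 Mb. H3K9ac was closer between the lines, with 19044 and 17000 peaks, a ratio of 0.893, covering 34.2 and 30.1 Mb. Among stronger H3K9ac peaks the number ratio was nearer 1. It was 0.953 and 0.960 with a −log10 q of at least 2 and 5, and 0.979 with a fold enrichment of at least 3.5. H3K27me3 peaks numbered 30117 in shCTRL and 39795 in shMSK1, a ratio of 1.32, and their covered length was 75.5 and 111 Mb. For H3K9me3 there were 54234 and 67913 peaks, a ratio of 1.252, covering 144 and 242 Mb. The mean fold enrichment of the peaks was 4.35 in shCTRL and 4.47 in shMSK1 for H3K9ac, and 2.75 and 3.16 for H3K27ac. It was 2.46 and 2.42 for H3K27me3, and 2.38 and 2.41 for H3K9me3.

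**Figure D1:**
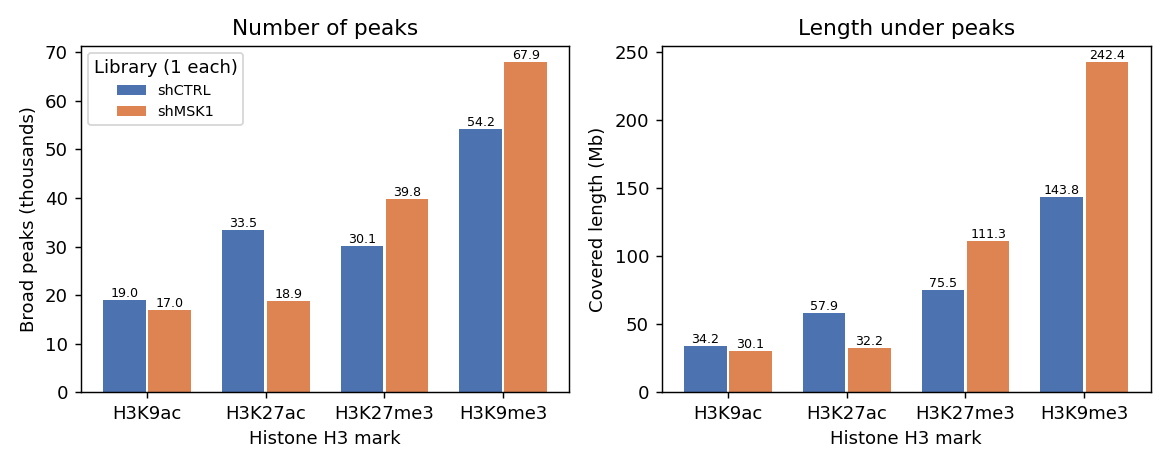
Bars give the number of broad peaks in units of 1000 (left) and the length they cover in Mb (right) for each histone mark, in the 1 shCTRL library (blue) and the 1 shMSK1 library (orange); there are no error bars because each bar is 1 library. Both acetylation marks have lower bars in shMSK1, most for H3K27ac (33490 against 18878 peaks), and both methylation marks have higher ones, most in length for H3K9me3 (144 against 242 Mb).

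H3K27ac was the acetylation mark that differed most, and the difference lay in its weaker peaks and its long stretches. Of the shCTRL H3K27ac peaks, 45.3% (44.8 to 45.9) were overlapped by an shMSK1 peak, against a mean of 2.89% for randomly rotated peaks. In the other direction, 83.6% (83.1 to 84.2) of the shMSK1 peaks were overlapped in shCTRL. The first share was 71.3% with a −log10 q of at least 2 in both lists and 76.5% with at least 5, and with lists of equal length the shares were 69.2% and 72.6%. The 18308 peaks found only in shCTRL had a median fold enrichment of 2.32, and the 15182 overlapped ones 3.12. Among the 6894 shCTRL peaks with a −log10 q of at least 5, 99.2% had an shMSK1 peak. Stretches of at least 10 kb, formed by joining peaks less than 3 kb apart, numbered 1108 in shCTRL and 430 in shMSK1. Of the 1108, 1042 still held an shMSK1 peak, but the median share of a stretch under shMSK1 peaks was 36.5%, against 75.0% under shCTRL peaks. The ratio of peak numbers was 0.893 at a −log10 q of at least 5 and turned to 1.04 among peaks with a fold enrichment of at least 3.5.

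The H3K27ac peaks without H3K9ac differed more between the lines than those that carried it. In shCTRL, 14593 H3K27ac peaks overlapped an H3K9ac peak, and 85.4% (84.8 to 86.0) of these had an H3K27ac peak in shMSK1. Of the 18897 without H3K9ac, 14.4% (13.9 to 14.9) had one. H3K27ac peaks with H3K9ac in the same library numbered 14593 and 12744, a ratio of 0.873. Those without H3K9ac numbered 18897 and 6134, a ratio of 0.325. Peaks with H3K9ac also had a higher median fold enrichment in shCTRL, 3.18 against 2.32. Within the fifth of 10 deciles of shCTRL fold enrichment, 57.4% of the peaks with H3K9ac and 14.5% of those without were overlapped in shMSK1.

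**Figure D2:**
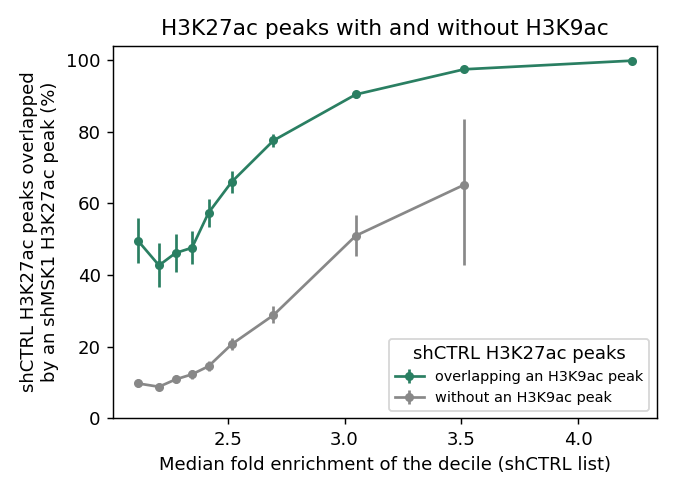
Each point gives the percentage of shCTRL H3K27ac peaks overlapped by an shMSK1 H3K27ac peak (y axis) in 1 decile of the shCTRL list ranked by fold enrichment, placed at that decile's median fold enrichment (x axis); bars are exact 95% intervals and groups under 20 peaks are left out. Peaks overlapping H3K9ac (green) lie above those without it (grey) at each of the 9 points they share, and both are highest at the highest fold enrichment plotted.

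The widest H3K27ac peaks found only in shCTRL spanned regions with no H3K27ac or methylation peak in shMSK1. The widest lay on chromosome 7 at 2103286 to 2113983, with a fold enrichment of 2.31 over 10698 bp, and also held 1150 bp of H3K9ac in shCTRL and none in shMSK1. The next lay on chromosome 20 at 17612884 to 17622265 (9382 bp, fold enrichment 2.48) and on chromosome 9 at 131670724 to 131680071 (9348 bp, fold enrichment 2.25). Neither had an H3K9ac, H3K27me3 or H3K9me3 peak in either line. The widest H3K27ac peak found only in shMSK1 was shorter, 4833 bp on chromosome 17 at 43471800 to 43476632. One on chromosome 5 at 43429438 to 43433730 (4293 bp) coincided with 1489 bp of H3K9ac that was also present only in shMSK1.

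H3K9ac peaks were largely in the same places in both lines. Of the shCTRL peaks, 80.1% (79.5 to 80.7) were overlapped in shMSK1, and of the shMSK1 peaks 90.2% (89.7 to 90.6) in shCTRL, with chance means of 2.53% and 2.80%. Covered bases common to both lists made up 69.0% of all bases covered in either, compared with 39.5% for H3K27ac. The widest H3K9ac peak of each line covered nearly the same stretch of chromosome 12, 116692379 to 116722503 in shCTRL and 116692659 to 116723856 in shMSK1. The widest peak found only in shCTRL was on chromosome 7 at 80133866 to 80141148, 7283 bp with a fold enrichment of 3.04, and no other mark was called there in either line. On chromosome 11, a 3201 bp peak at 90577300 to 90580500 appeared only in shMSK1, together with H3K27ac over its whole length.

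H3K9me3 covered more of the genome in shMSK1. Bases under shMSK1 and not under shCTRL peaks amounted to 122 Mb, of which 63.8% belonged to peaks that overlapped an shCTRL peak and 36.2% to peaks found only in shMSK1. Joined domains of at least 50 kb numbered 443 in shCTRL and 992 in shMSK1, spanning 41.002 and 105.525 Mb, and the 992 held 22.9% of those 122 Mb. Each of the 992 contained an shCTRL H3K9me3 peak, against a mean of 44.7% after rotation of the shCTRL peaks, and in 713 of them (71.9%, 69.0 to 74.7) shCTRL peaks covered at least 50% of the domain. The median share under shCTRL peaks was 61.6%, against 87.5% under shMSK1 peaks and at most 0.620% after rotation. All 443 shCTRL domains were covered by shMSK1 peaks over at least 50% of their length. The widest H3K9me3 peak of both lines lay on chromosome 8, at 139568200 to 139698721 in shCTRL and, extending on both sides, at 139460010 to 139716240 in shMSK1. The longest joined domain in shMSK1 spanned 732 kb of chromosome 20 from 59194246 to 59925836. The background level from short H3K9ac peaks was 7.69 on chromosome 8 and 7.53 on chromosome 20. Over the chromosomes it ran from 5.16 on chromosome 18 to 7.87 on chromosome 14. Whether more DNA copies or mappable reads shaped these domains was not tested. With a −log10 q of at least 2, the ratio of peak numbers was 2.12 and that of covered length 2.65. With a −log10 p of at least 4 in both lists, these ratios were 1.19 and 1.83. The same q limit corresponded to a lower p limit in shMSK1, since the lowest −log10 p was 2.75 in shCTRL and 2.45 in shMSK1.

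Of the shCTRL H3K9me3 peaks, 84.7% (84.4 to 85.0) were overlapped in shMSK1, whereas 50.2% (49.8 to 50.6) of the shMSK1 peaks were overlapped in shCTRL. The chance means were 15.0% and 10.3%. The latter share was 30.9% with a −log10 q of at least 2 in both lists and 14.8% with at least 5. At the last limit, 71 shCTRL peaks were left to match 298 in shMSK1. Of these 298, 97.3% were overlapped by a peak of the full shCTRL list. Of the 33830 H3K9me3 peaks found only in shMSK1, 55.8% lay within 10 kb of an shCTRL H3K9me3 peak, against 21.2% after rotation. The widest of these lay on chromosome 11 at 40899380 to 40913200, 13821 bp with a fold enrichment of 2.33, and no other mark was called there in either line. The same held on chromosome 19 at 24402437 to 24415117 (12681 bp). On chromosome 5 at 3174613 to 3186904, the new H3K9me3 peak of 12292 bp lay over H3K27me3 that was present in both lines (9639 bp in shCTRL and 8414 bp in shMSK1). The widest H3K9me3 peak found only in shCTRL measured 5184 bp, on chromosome 8 at 123271835 to 123277018.

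H3K27me3 also covered more of the genome in shMSK1. Bases under shMSK1 and not under shCTRL peaks amounted to 52.9 Mb, with 55.8% in peaks that overlapped an shCTRL peak and 44.2% in peaks found only in shMSK1. Domains of at least 50 kb numbered 120 in shCTRL and 213 in shMSK1, spanning 9.66 and 18.7 Mb, and the 213 held 6.08% of the 52.9 Mb. All 213 held an shCTRL H3K27me3 peak, against 28.3% after rotation, and the median share under shCTRL peaks was 72.5%. Of the shCTRL peaks, 76.0% (75.5 to 76.5) were overlapped in shMSK1, and of the shMSK1 peaks 50.3% (49.8 to 50.8) in shCTRL, with chance means of 7.83% and 5.71%. Among 19778 peaks found only in shMSK1, 57.0% lay within 10 kb of an shCTRL peak, against 14.1% after rotation. Among the 7231 found only in shCTRL, 77.1% lay within 10 kb of an shMSK1 peak, against 18.3%. The widest H3K27me3 peaks of the lines overlapped on chromosome 17, at 77169550 to 77340263 in shCTRL and 77273634 to 77440108 in shMSK1. The widest found only in shMSK1 lay on chromosome 14 at 36660639 to 36671381 (10743 bp, fold enrichment 2.21). The other two lay within regions that carried H3K9me3 in both lines, on chromosome 10 at 50115755 to 50125716 and on chromosome 7 at 71568166 to 71578068. The first of these also held 1448 bp of H3K27ac in shCTRL and none in shMSK1. The widest found only in shCTRL was 4494 bp, on chromosome 16 at 5433921 to 5438414.

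**Figure D3:**
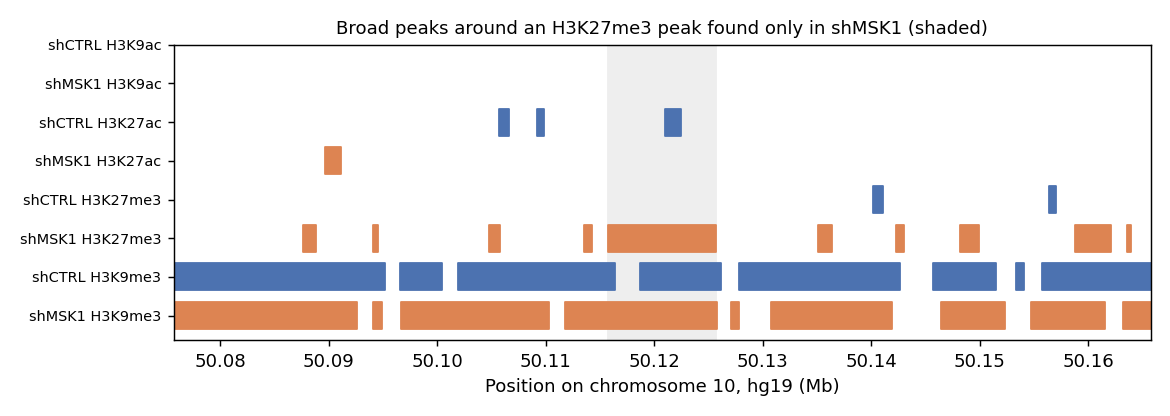
Blocks are broad peaks of the 4 marks in shCTRL (blue) and shMSK1 (orange) along chromosome 10 (hg19, Mb), 40 kb either side of the H3K27me3 peak at 50115755 to 50125716 found only in shMSK1 (shaded). In this window H3K27me3 peaks covered 1.53 kb in shCTRL and 20.8 kb in shMSK1, H3K9me3 covered 76.5 and 72.7 kb, and no H3K9ac peak was called in either line.

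**Figure D4:**
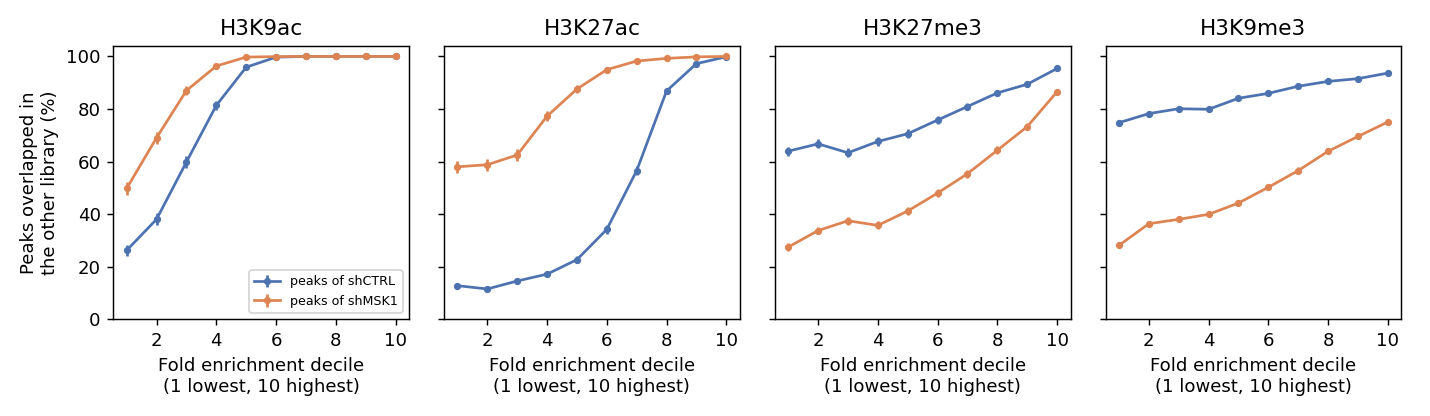
For each mark, peaks of a library were ranked by fold enrichment and divided into deciles (x axis), and the y axis gives the percentage overlapped by a peak of the other library, with exact 95% intervals; blue points are peaks of shCTRL and orange points peaks of shMSK1. For H3K9me3 the strongest decile of shMSK1 peaks was overlapped in 75.1% of cases and the strongest decile of shCTRL peaks in 93.7%.

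The differences were shared by the chromosomes. H3K9ac and H3K27ac peaks were fewer in shMSK1 on all 23 chromosomes compared, the autosomes and X. The H3K27ac ratio ran from 0.435 on chromosome 20 to 0.868 on chromosome 13. H3K27me3 peaks were more numerous on all 23, with ratios from 1.16 on chromosome 20 to 1.91 on chromosome 18. H3K9me3 peaks were more numerous on 22, the exception being chromosome 20 with a ratio of 0.979, where the covered length was still 1.38 times that of shCTRL. The highest H3K9me3 ratio, 8.60 on chromosome 18, rested on 20 peaks in shCTRL and 172 in shMSK1.

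**Figure D5:**
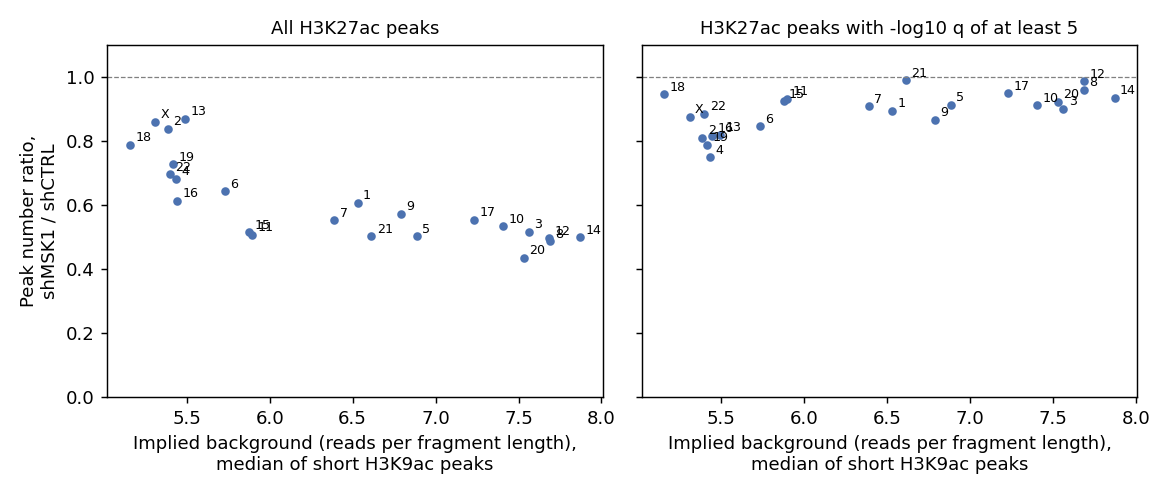
Each point is 1 chromosome, labelled, with the ratio of H3K27ac peak numbers in shMSK1 to shCTRL (y axis) against a background level in reads per fragment length derived from short H3K9ac peaks (x axis), for all peaks (left) and for those with a −log10 q of at least 5 (right); the dashed line marks a ratio of 1. All 23 ratios lie below 1 on the left, from 0.435 on chromosome 20 to 0.868 on chromosome 13, and they are lower where the background level is higher.

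The marks also overlapped one another differently in the lines. H3K9ac peaks carried H3K27ac in 79.4% (78.8 to 80.0) of cases in shCTRL and 76.2% (75.6 to 76.9) in shMSK1. The reverse share, H3K27ac peaks carrying H3K9ac, was 43.6% (43.0 to 44.1) and 67.5% (66.8 to 68.2). H3K27ac peaks overlapped H3K27me3 in 10.5% (10.1 to 10.8) of cases in shCTRL, 2.04 times the chance mean, and in 3.15% (2.91 to 3.41) in shMSK1, 0.468 times the chance mean. H3K27me3 peaks lay on H3K9me3 in 13.2% (12.8 to 13.6) of cases in shCTRL and 24.1% (23.7 to 24.5) in shMSK1, or 1.36 and 1.68 times chance. These shares count any peak that shares at least 1 bp. Counted in shared bases, the overlap was 0.905 times chance in shCTRL, within the range of the rotations, and 1.24 times in shMSK1.

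Few of the acetylated sites found only in shCTRL carried a methylation peak found only in shMSK1. Of the 18308 shCTRL-only H3K27ac peaks, 2.18% (1.97 to 2.40) overlapped an H3K27me3 peak found only in shMSK1, against 0.501% (0.395 to 0.626) of the H3K27ac peaks overlapped in both lines. Rotated peaks gave a mean of 1.81% for the first group, with a range of 1.502 to 2.229%, so the overlap lay within that range, near its upper end. Only methylation peaks touching no shCTRL peak of that mark were counted, so bases gained in peaks that overlapped an shCTRL peak were left out. For new H3K9me3 the shares were 1.47% (1.31 to 1.66) and 0.415% (0.319 to 0.531), below the 2.79% of rotated peaks for the first group. Of the 3789 shCTRL-only H3K9ac peaks, 1.29% (0.958 to 1.71) overlapped new H3K27me3 and 0.290% (0.145 to 0.519) new H3K9me3, with chance means of 1.5004% and 2.35%. The corresponding shares for H3K9ac peaks overlapped in both lines were 0.695% and 0.0721%. H3K27me3 was already present in shCTRL at 17.8% (17.2 to 18.3) of the shCTRL-only H3K27ac peaks and at 1.67% (1.48 to 1.89) of the overlapped ones. Counting every H3K27me3 peak of shMSK1, 18.7% (18.2 to 19.3) of the shCTRL-only H3K27ac peaks were overlapped, 2.76 times chance, and for every H3K9me3 peak of shMSK1 the share was 11.99% (11.5 to 12.5), 0.965 times chance.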

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

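The direction of the difference in peak number was opposite for acetylation and methylation. The shMSK1 to shCTRL ratio was 0.893 for H3K9ac and 0.564 for H3K27ac, and 1.32 for H3K27me3 and 1.252 for H3K9me3. This difference between marks was not tested, because each ratio comes from 1 library per cell line. The tests weighed here on calling sensitivity, loss without H3K9ac, background levels of the methylation libraries, peak number and covered length at a fixed p limit, and confinement to some chromosomes were chosen after the results were seen.

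For the lower number of H3K27ac peaks in shMSK1, a lower sensitivity of peak calling in that library may contribute, since the ratio was 1.04 among peaks with a fold enrichment of at least 3.5 and its background level was 0.7999 times that of shCTRL (95% bootstrap interval 0.794 to 0.806), though the shMSK1 level may be too low. It cannot be told apart from an effect, because the covered length stayed lower in shMSK1. The length ratio was 0.927 at that limit and 0.776 at a −log10 q of at least 5. The 90th percentile of fold enrichment was 4.20 in shMSK1 against 3.82, but the shCTRL list held more weak peaks, which lowers its percentile. Among peaks overlapped in the other line the median fold enrichment was 3.12 in shCTRL and 3.15 in shMSK1. Weak regional background called as peaks in shCTRL may contribute, since shCTRL-only H3K27ac peaks overlapped shCTRL H3K27me3 3.65 times as often as rotated peaks did, above all 100 rotations. Loss of H3K27ac at sites without H3K9ac could also give the pattern: at matched fold enrichment the share overlapped in shMSK1 was 39.2 percentage points lower without H3K9ac, on average over 9 deciles of the list, with a range of 32.3 to 48.8, where the highest of the 9 held 23 peaks without H3K9ac. Sites with H3K9ac may also more often be true sites, so this loss cannot be told apart from background, and an effect of the knockdown stays open.

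The greater methylated length in shMSK1 was weighed against background level, p limit and sensitivity of calling. For H3K9me3 the derived background was lower in shMSK1, with a ratio to shCTRL of 0.930 (95% bootstrap interval 0.929 to 0.930). This goes against a higher background in that library. The interval comes from 1 library per line, as does that for H3K27ac, and does not cover spread between libraries. The short peaks also passed different p limits. At 1.08 for H3K27me3, where the shCTRL level may be too low, a higher background cannot be told apart from an effect. At a −log10 p of at least 4 the ratio of peak numbers was 1.17 for H3K27me3 and 1.19 for H3K9me3, between the bounds set for it. The ratio of covered length was 1.44 and 1.83, above the bound set against unequal p limits as its whole cause. But this limit drops whole peaks and leaves the edges of the others as called under the unequal p limits. It therefore cannot tell whether unequal p limits gave the greater length. Sensitivity of calling cannot be told apart from an effect, because the peaks with a fold enrichment of at least 3.5, with number ratios of 1.73 and 3.91, made up at most 0.508% of any of these lists. Immunoprecipitation efficiency and an effect of the knockdown stay open, as both differ with the 1 library per line.

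The H3K27ac ratio was uneven between chromosomes, from 0.435 to 0.868. It was lower where the background level implied by H3K9ac peaks was higher, with a Spearman rho of -0.859 (permutation p = 1e-05, the smallest that 100000 permutations can give; Benjamini-Hochberg adjusted 5e-05 over 5 relations) and a Pearson r of -0.787 (permutation p = 2e-05, adjusted 0.0001), or -0.775 without the 2 chromosomes farthest from the median, all two-sided over 23 chromosomes that are not independent replicates. This is consistent with more weak peaks being called in shCTRL where more DNA copies or mappable reads raise the background. Among peaks with a −log10 q of at least 5 the relation had the opposite sign, with a rho of 0.588 (permutation p = 0.00379, adjusted 0.00632) and an r of 0.624 (permutation p = 0.00168, adjusted 0.00418), and 0.587 without the 2 farthest. A knockdown effect on weak peaks of some chromosomes cannot be told apart from this: at that limit the 6 chromosomes with the lowest ratios had a median 0.0997 above that of the 6 highest, 0.947 against 0.847, but these peaks are 20.6% of the shCTRL list and the strongest in it.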

How the results depend on the processing

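No paired analysis was possible because each group holds 1 library. The limits on −log10 p and fold enrichment were chosen after seeing the data; the rest were fixed before. Of 76 alternative values, 34 stayed within 1.5 times the number or length ratio, or within the counting interval of a share or difference. Another 41 moved beyond that without turning direction, and 1 turned direction. The bound of 1.5 times is wide. The H3K27ac number ratio of 0.564 stayed within it at 0.822, with a −log10 q of at least 2. It also did at 0.815, with a −log10 p of at least 4. The promoter and gene list alternatives were not run, for want of an annotation in the build of the peaks. Read depth is unknown, so what it limits was not measured. At a −log10 q of at least 5, ratios rest on few methylation peaks, 71 for shCTRL H3K9me3. The cause of the shifts was not tested except as given among the flagged results.

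Among peaks with a fold enrichment of at least 3.5, the H3K27ac number ratio turned from 0.564 to 1.04 (5099 and 5326 peaks) and its length ratio was 0.927; the length ratio was 3.13 for H3K27me3 and 6.62 for H3K9me3, and the H3K9me3 number ratio 3.91. At a −log10 q of at least 5 the number ratio was 0.893 for H3K27ac and 4.20 for H3K9me3, with a length ratio of 5.83 for H3K9me3. At a −log10 q of at least 2 the H3K9me3 number ratio was 2.12 and its length ratio 2.65. At a −log10 p of at least 4 the H3K9me3 ratios of number and length were 1.19 and 1.83.

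Shares are given in the order H3K9ac, H3K27ac, H3K27me3 and H3K9me3. When 50% of a peak had to be covered, the shCTRL peaks overlapped were 74.7, 34.96, 63.3 and 73.8%. At a −log10 q of at least 2 in both lists they were 88.0, 71.3, 76.2 and 81.1%, and the shMSK1 peaks overlapped 92.7, 88.5, 45.8 and 30.9%. At a −log10 q of at least 5 they were 91.8, 76.5, 74.4 and 63.4% of shCTRL peaks and 95.9, 86.3, 48.6 and 14.8% of shMSK1 peaks. With lists of equal length they were 86.6, 69.2, 66.5 and 76.9% of shCTRL peaks and 87.1, 72.6, 56.3 and 54.7% of shMSK1 peaks. Of the shMSK1 H3K9me3 peaks with a −log10 q of at least 5, 97.3% were overlapped by a peak of the full shCTRL list.

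Shared acetylation peaks are by definition acetylated in shMSK1. In that line H3K27ac peaks overlapped H3K27me3 0.468 times and H3K9me3 0.169 times as often as rotated peaks did. An excess of new methylation at shCTRL-only over shared acetylation peaks is therefore partly built in. Its sign is no evidence of an exchange between marks. This excess kept its sign. For H3K27ac and H3K27me3 it was 1.68 percentage points, 0.928 at 50% coverage and 1.09 at a −log10 q of at least 2. For H3K27ac and H3K9me3 it was 1.06, 0.682 and 0.739 points, and for H3K9ac and H3K27me3 it was 0.598 and, at a −log10 q of at least 2, 1.62 points.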

Other observations

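Regions under both methylation marks were more extensive in shMSK1, a comparison that, like the others given here except the overlap with methylation in shCTRL, was chosen after seeing the data. Bases covered by H3K27me3 and H3K9me3 together amounted to 4.24 Mb in shCTRL and 13.3 Mb in shMSK1, 3.14 times as much. Much of this ratio followed from the longer lists, since the product of the length ratios of the marks was 2.49 and rotated peaks gave a ratio of 2.28. The joint length was 0.905 times the mean of 100 rotations in shCTRL, within their range of 3.21 to 6.26 Mb, and 1.24 times in shMSK1, above their highest of 12.8 Mb. Of the shMSK1 bases under both marks, 16.8% were under both in shCTRL, 28.9% under H3K27me3 alone, 20.2% under H3K9me3 alone and 34.1% under neither. Of the shCTRL bases under both marks, 52.6% were under both in shMSK1. The cell line is a population, so peaks at the same place do not show that both marks lay on the same molecule.

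The H3K9ac peaks without H3K27ac numbered 3926 in shCTRL and 4041 in shMSK1, a ratio of 1.03, while those with H3K27ac numbered 15118 and 12959, a ratio of 0.857. Of the shCTRL H3K9ac peaks without H3K27ac, 47.8% (46.3 to 49.4) were overlapped by an shMSK1 H3K9ac peak, against 88.5% (88.0 to 89.0) of those with it. Those without it were weaker, with a median fold enrichment of 2.59 against 4.75. Within deciles of fold enrichment the gap was smaller, 49.7 against 67.1% in decile 3 and 90.4 against 97.7% in decile 5. The longest joined H3K27ac stretch of shMSK1, on chromosome 16 at 85632051 to 85701871, contained the widest shCTRL H3K27ac peak, at 85654764 to 85701068, and all 430 shMSK1 stretches of at least 10 kb held an shCTRL peak. The shCTRL-only H3K9ac peaks also lay on shCTRL H3K27me3 more often than rotated peaks, 7.02% (6.23 to 7.88) against a mean of 4.18%, and on shCTRL H3K9me3 less often, 1.56% (1.187 to 2.004) against 7.12%.

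Over the 23 chromosomes, the H3K9me3 number ratio was also lower where the background level was higher. The rho was -0.732 (permutation p = 0.00014, adjusted 0.00035) and the r -0.401 (permutation p = 0.00251, adjusted 0.00418), or -0.397 without the 2 farthest chromosomes. In each relation the 2 were the farthest in background level, not in ratio. Chromosome 18, with an H3K9me3 ratio of 8.60 from 20 and 172 peaks, was therefore kept. The r of -0.397 does not check how much that chromosome weighs. For H3K9ac the rho was -0.473 (permutation p = 0.0235, adjusted 0.0294) and the r -0.379 (permutation p = 0.0769, adjusted 0.0769), or -0.406 without the 2 farthest. For H3K27me3 the rho was -0.350 (permutation p = 0.102, adjusted 0.102) and the r -0.433 (permutation p = 0.0284, adjusted 0.0355), or -0.448 without the 2 farthest. These belong to the same 5 relations, adjusted by Benjamini-Hochberg, are two-sided, and are over chromosomes that are not independent replicates.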
